A study of Mus musculus with 2 samples.

How the data were processed

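H3K9ac ChIP-seq was measured in 2 biological replicates of midbrain from mouse embryos at embryonic day 11.5, pools of 109 and 88 embryos of both sexes. Replicate numbers were taken from the labels. Both samples belong to 1 group, and the pooling leaves no information on single embryos or litters.

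The authors deposited 4 peak lists in narrowPeak format on the mm10 build: 1 list for each replicate, 1 list called on both replicates together, and 1 list of replicated peaks, which the deposited records derive from the other 3. Each replicate's list was derived from filtered alignments and 2 control files, per the deposited records. The aligner, the peak caller, its version and its threshold are not given in the sources used here. In each deposited list, column 7 holds a linear ratio, the fold enrichment of the peak over its background, and is the authors' own value. Column 8 of the deposited lists holds −log10 of the authors' p-value, and it was used only to take the most significant 50% of peaks. The meaning of column 7 was checked on the values: in the list of replicate 1, the values of 14702 weak peaks (25.7%) equal (reads + 1)/(background + 1) for a background of 2.39, and their p equals the Poisson tail of that pileup (tolerance 0.0002 on −log10 p). For replicate 2 a read was worth 0.959 and the background was 2.77. In the pooled list a read was worth 0.506. From the weights of replicate 2 and of the pooled list, the depth of replicate 1 relative to replicate 2 was inferred as 0.894. This holds only if both replicates and the pooled data were scaled to the same control. Read totals are unknown, so no interval for counting error could be given for a single peak. All 35256 replicated peaks are identical to peaks of the pooled list, 85.4% of which were kept.

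Genes were the 21938 protein-coding genes of GENCODE release M21 on chromosomes 1 to 19, X and Y, with 93513 transcript starts, on the same build. Peaks on unplaced scaffolds (5 in the replicated list) entered no comparison. A gene was marked when a peak lay within 1 kb of any of its transcript starts, and its enrichment is that of the strongest such peak. Peak locations were assigned in the order promoter, other exon, intron and intergenic. Peaks of the replicates were shared when an overlap covered at least 50% of either peak (bedtools 2.31.1), and the share was set beside 100 random placements within chromosomes. The observed/expected CpG ratio was taken over 500 bp on each side of the gene's 5' end. Domains joined peaks at most 1 kb apart, and a gene's width is that of its widest promoter domain. Distal peaks lay more than 1 kb from every protein-coding start and were assigned to the start nearest to their centre.

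The gene lists (20 lists of tissue, region, cell type and pathway genes, and 11 gene families), the tests and the alternatives were fixed before the data were examined. The lists overlap, so their tests are not independent. Shares of marked genes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 31 lists, and with exact binomial intervals of 95%. The 5 planned comparisons between lists were adjusted among themselves. Widths were compared with 100000 random sets of marked genes for lists with at least 5 marked members. Distal peaks were compared with 100000 random lists of protein-coding genes, marked or not, drawn within 10 bins of the length of genome nearest to each gene. The permutation tests were two-sided, and alternatives used 10000 resamples. The threshold was an adjusted p of 0.05. Correlations across peaks are given without p. Genes were named by a rule fixed with the lists: the 4 marked members of each list with the highest enrichment and its first 3 unmarked members in alphabetical order, any member of the midbrain and dopaminergic lists, the 10 genes with the widest domains, the 5 strongest distal peaks and the 5 genes with most of them, up to 5 list members per replicate with a peak in that replicate alone, and the references Actb, Gapdh, Hbb-bt, Alb and Myod1. Partner genes of shared promoter peaks were named after their values were seen.

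Alternatives replaced the replicated list by that of each replicate, by the pooled list or by its most significant 50%, moved the promoter distance to 500 or 2500 bp, took the annotated 5' end alone, joined domains over 3 kb or not at all, moved the distal distance to 2500 bp or 5 kb, changed the overlap rule, and drew random lists within 5 bins of CpG ratio. Added after the data were examined were the omission of promoter peaks shared by neighbouring genes, random sets within 5 bins of transcript start number, and the X comparison without nasal receptor genes or without copied promoters. Copied promoters were defined by the 31-base words in the 500 bp on each side of the 5' end. Over 50% of these words had to occur at another position in the windows of protein-coding promoters, the promoter's own window included.

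The tests were first tested on simulated values assigned to the real genes. These values were independent between genes and of CpG content, with evenly spread distal peaks. Real peaks follow CpG content and are clumped, so the rates below hold only for such simulated data. Of 15 simulated lists of 30 genes with planted differences, 13 passed the threshold in the marking test, 14 in the width test (widths 2 times larger) and 15 in the distal test (2.5 times more peaks). Of 15 lists tested beside them with nothing planted, 0, 2 and 1 passed the adjusted threshold. Of a further 200 such lists, 3.5%, 7.5% and 2% had an unadjusted p under 0.05 in these tests, so the width test passed somewhat more null lists than its nominal 5%. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.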

Results

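Acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters, was profiled by ChIP-seq in the midbrain of mouse embryos of the C57BL/6 substrain B6NCrl at embryonic day 11.5. At this stage the midbrain holds dividing neural progenitors, newborn neurons and the isthmic organizer at its caudal border. The group comprised 2 biological replicates of mixed sex, a pool of 109 embryos for replicate 1 and a pool of 88 embryos for replicate 2. There was no second tissue, stage or treatment, so the comparisons were between replicates, between genomic locations and between gene lists within this tissue. The list of replicate 1 held 57265 peaks with a median width of 305 bp, and that of replicate 2 held 49589 peaks with a median width of 428 bp. The replicated list, which the deposited records derive from the lists of each replicate and of the pooled data, held 35256 peaks that covered 32.1 Mb, or 1.18% of the genome. Of those on the assembled chromosomes, 84.8% overlapped a peak of both replicates by at least 50% of either peak, 1214 a peak of replicate 1 alone, 4067 a peak of replicate 2 alone and 93 neither, so a replicated peak is not always listed in both. Read totals were not among the deposited values, so the depth of each library is known only as a ratio. The pileup scaling of the weak peaks placed replicate 1 at 0.894 of the depth of replicate 2. This assumes that both replicates and the pooled data were scaled against the same control reads. The enrichment of a peak over its background is the authors' own value throughout, and it was used to describe and rank peaks within a list. Peaks and genes are not independent replicates, so the tests below describe how peaks are spread over genes in these samples, not variation between litters.

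The replicates were compared first. Nearly all strong H3K9ac peaks were found in both pools, and the peaks of a single pool were weak, narrow and mostly away from promoters. Of the replicate 1 peaks on the assembled chromosomes, 34815 of 57260 (60.8%) were shared with replicate 2, against a mean of 2.00% after random placement. Of the replicate 2 peaks, 28416 of 49583 (57.3%) were shared, against 2.30% after random placement. In the top 25% of peaks by enrichment, 99.99% and 99.94% were shared in replicates 1 and 2. In the bottom 25%, 29.9% and 19.2% were. Peaks found in replicate 1 alone had a median enrichment of 3.16, compared with 4.88 for its shared peaks, and 14.2% of them lay at promoters compared with 60.1%. Peaks found in replicate 2 alone had a median enrichment of 3.32, compared with 7.39 for its shared peaks, and 17.5% lay at promoters compared with 60.2%. The difference in promoter share gave a −log10 p of 2778 in replicate 1 and 2099 in replicate 2 (one-sided tail of Fisher's exact test, since the two-sided p was too small to be represented). Across 27919 pairs of overlapping peaks, enrichment correlated with a Spearman rho of 0.893 and a Pearson r of 0.916 on the log2 scale, a correlation across peaks, which are not independent. When the overlap had to reach 50% of both peaks instead of either, the shared part of replicate 1 was 38%. Among members of the gene lists, 21 had a promoter peak in replicate 1 alone and 11 in replicate 2 alone. They included Eomes, a T-box factor of intermediate progenitors of the cortex, at an enrichment of 3.24 in replicate 1, and Corin, a floor plate protease, at 3.23 in replicate 2.

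H3K9ac was concentrated at the promoters of protein-coding genes. Promoters, taken as the sequence within 1 kb of a transcript start, held 19078 replicated peaks (54.1%), 9.95 times the share of randomly placed peaks (5.44%, range 5.15 to 5.71 over 100 placements). The remaining peaks lay in other exons (4.73%, against 6.40% placed), in introns (19%, against 30.2%) and between genes (22.2%, against 58.0%). Promoter peaks had a median width of 1040 bp and a median enrichment of 9.24, whereas intron peaks had medians of 358 bp and 3.34. Of the 1000 peaks with the highest enrichment, 96.8% lay at promoters. The housekeeping references were among them: the peak at Actb, which encodes cytoplasmic beta-actin, had an enrichment of 42.1, and that at Gapdh, a glycolytic enzyme, 29.8. The beta-globin gene Hbb-bt, the liver gene Alb and the muscle regulator Myod1, used as references from other tissues, had no promoter peak in any of the lists.

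**Figure D1:**
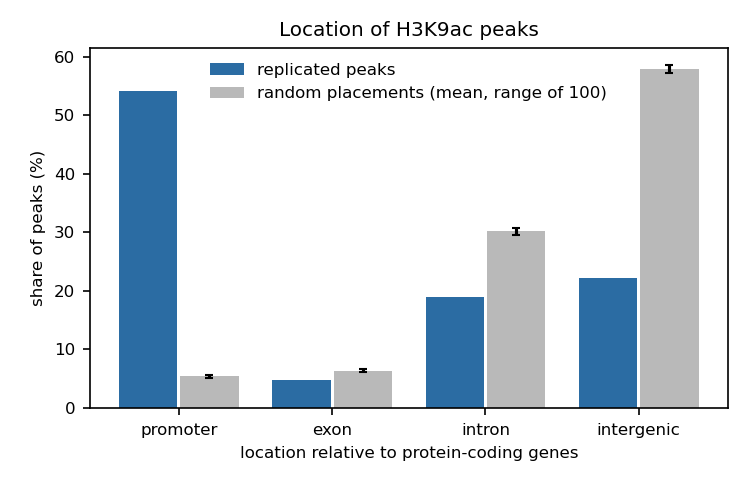
Share of the replicated H3K9ac peaks (blue) in promoters, other exons, introns and intergenic sequence, in percent, beside the mean share over 100 random placements (grey, bars showing the range). Promoters held 54.1% of the peaks and 5.44% of the placed ones.

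Of 21938 protein-coding genes, 14068 carried a replicated peak at a promoter (64.1%, 95% exact binomial interval 63.5 to 64.8). These genes are called marked in what follows. Replicate 1 alone gave 14303 marked genes and replicate 2 alone 14345, of which 13968 were common to both. Marked promoters were rich in CpG dinucleotides. Their median observed/expected CpG ratio was 0.713 (interquartile range 0.553 to 0.831), compared with 0.177 (0.110 to 0.280) at unmarked promoters, and their median GC content was 58.7% compared with 45.6%. Across 5 equal bins of increasing CpG ratio, 9.28%, 32.2%, 84.0%, 96.6% and 98.6% of genes were marked. CpG content therefore entered the gene list comparisons as an alternative background.

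Regulators that pattern the midbrain and the isthmus were almost completely marked. Of 38 members, 37 carried a replicated promoter peak (97.4%, interval 86.2 to 99.9), compared with 64.1% of all other genes (Fisher's exact test, two-sided, adjusted p = 3.2e-06 over 31 lists and families). The strongest member was Otx2, the homeobox gene that specifies forebrain and midbrain. Its promoter peak, starting at position 48659953 of chromosome 14 in the mm10 build, had an enrichment of 32.8 (28.3 in replicate 1 and 40.5 in replicate 2) and stood at percentile 99.6 of all replicated peaks. The Iroquois gene Irx3 reached 29.9, the TALE homeobox gene Meis1 27.5 and Irx1 24.8. The engrailed genes En1 and En2, expressed across the midbrain and hindbrain boundary, had values of 13 and 14.8, and the dorsal midbrain genes Pax3 and Pax7 had 15 and 10.1. Among signals of the isthmus and the dorsal midline, the growth factor genes Fgf18 and Fgf8 had an enrichment of 8.57 and 4.78, Wnt1 4.65 and Wnt3a 3.55, between percentiles 30.7 and 68.7 of all peaks. Gbx2, the hindbrain counterpart of Otx2 at the boundary, had 4.35. Fgf17 was the unmarked member, with a peak of 3.47 in replicate 1 alone. When random lists were drawn within the CpG bins, 34.7 marked members were expected and the list no longer passed the threshold (permutation test, adjusted p = 0.226).

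The Hox genes, which pattern the hindbrain, spinal cord and more caudal tissues, formed the opposite extreme, and the forebrain list lay between. None of the 39 Hox genes was marked (0%, interval 0 to 9.03, Fisher's exact adjusted p = 2.53e-17), although 33.3 would be expected from their CpG content (permutation p = 1e-05, the smallest possible with 100000 resamples). Replicates 1 and 2 each listed a promoter peak at 2 Hox genes. Of 29 forebrain patterning genes, 23 were marked (79.3%), which did not differ from other genes by Fisher's exact test (adjusted p = 0.143). Their CpG content gave an expectation of 24.8, and the list did not differ from CpG-matched lists (permutation adjusted p = 0.42). Without CpG matching the list passed in replicate 1 alone (89.7%, Fisher's exact adjusted p = 0.00861) and within 2500 bp of a start (86.2%, adjusted p = 0.0268 by the same exact test), and with promoter peaks shared by neighbouring genes left out its 79.3% stood above the lowered share of other genes (adjusted p = 0.00376). The strongest were Bcl11b (23.3) and Satb2 (16.4), transcription factors of cortical projection neurons, followed by Lhx2 (8.30) and Sp8 (7.49), which is also in the midbrain list. Unmarked members included Fezf2 and Gsx2, regulators of deep-layer cortical neurons and of the ventral telencephalon. With the shared gene left out, 97.3% of midbrain genes and 78.6% of forebrain genes were marked, a difference of 18.7 points that did not pass the threshold (Fisher's exact p = 0.0365, adjusted p = 0.0609 over 5 pairs). In the most significant 50% of the replicated peaks the difference was 57.9 points (adjusted p = 5.9e-06), since only 31% of forebrain genes stayed marked, below other genes (Fisher's exact adjusted p = 0.00645). With the annotated 5' end of each gene as its promoter the difference was 26.7 points (Fisher's exact adjusted p = 0.0111). Midbrain and Hox genes differed by 97.4 points (Fisher's exact adjusted p = 1.47e-20) and forebrain and Hox genes by 79.3 points (adjusted p = 1.48e-12).

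**Figure D2:**
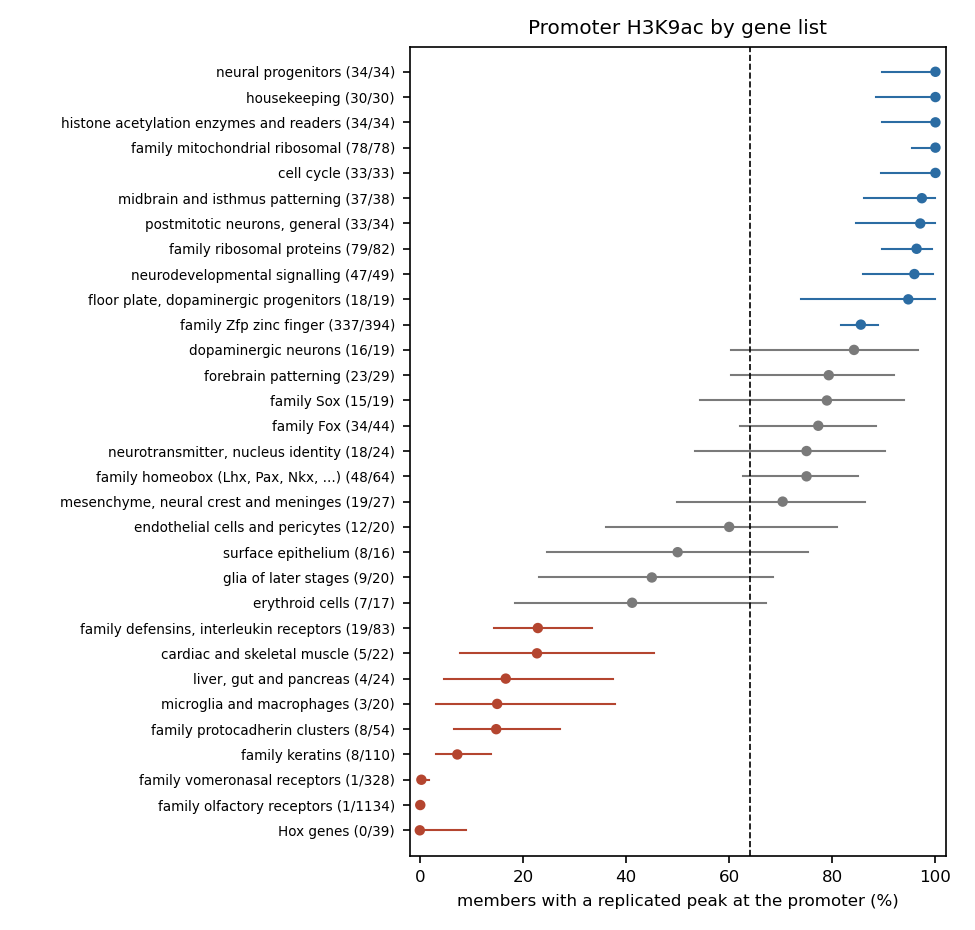
Percentage of the members of each gene list or family with a replicated H3K9ac peak at a promoter, with 95% exact binomial intervals (lines) and the number marked in brackets. Blue and red mark lists above and below all other genes at an adjusted p under 0.05 (Fisher's exact test), grey the rest, and the dashed line is the share of all protein-coding genes (64.1%).

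Genes of the ventral midline and of dopaminergic progenitors were marked almost throughout. Most genes of dopaminergic neurons were marked as well, but not Th. In the floor plate and progenitor list 18 of 19 genes were marked (94.7%, Fisher's exact adjusted p = 0.00526), which fell short of the threshold against CpG-matched lists (permutation adjusted p = 0.821). The Notch effector Hes1 (15.9), the axon guidance gene Ntn1 (15.9), Wnt5a (15.6) and the Hedgehog effector Gli2 (15.3) were its strongest members. Shh, the ventral morphogen itself, had an enrichment of 9.02, and the midline regulators Foxa1, Foxa2 and Lmx1a had 9.01, 8.43 and 7.59. Corin was not marked in the replicated list. In the dopaminergic neuron list 16 of 19 genes were marked (84.2%, interval 60.4 to 96.6, Fisher's exact adjusted p = 0.119). With promoter peaks shared by neighbouring genes left out for all genes, its share stayed at 84.2%. It then stood above the lowered share of other genes (Fisher's exact adjusted p = 0.0067). After Otx2, the highest values were those of the TALE factors Pbx3 (24.3) and Pbx1 (17.6) and of Nr4a2 (14.0), the nuclear receptor required for the dopaminergic fate. Pitx3, a later factor of these neurons, had 3.83, the vesicular monoamine transporter gene Slc18a2 4.78, the decarboxylase gene Ddc 4.57 and the dopamine transporter gene Slc6a3 2.53, at percentile 3.76 of all peaks. Th, the rate-limiting enzyme of dopamine synthesis, Aldh1a1 and Sncg had no promoter peak in either replicate. The shares of the progenitor and neuron lists differed by 10.5 points (Fisher's exact p = 0.604, adjusted p = 0.755). In the most significant 50% of peaks they differed by 36.8 points (Fisher's exact adjusted p = 0.0477), as Pitx3, Slc18a2 and Slc6a3 were among the genes that dropped out.

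Genes of dividing progenitors and of newborn neurons were almost all marked. All 34 neural progenitor genes were marked (100%, interval 89.7 to 100, Fisher's exact adjusted p = 1.26e-06), with the highest enrichment at Msi1 (37.7) and Msi2 (31.3), which encode RNA-binding proteins of neural stem cells, at Pou3f3 (33.4) and at the stem cell factor Sox2 (29.6). Of the 34 general neuronal genes 33 were marked (97.1%, Fisher's exact adjusted p = 1.29e-05), led by the Snail-related repressors Scrt1 (22.9) and Scrt2 (18.1), by Elavl3 (20.1), which encodes a neuronal RNA-binding protein, and by Stmn3 (18.3), a microtubule regulator. Neurod4 was unmarked. The progenitor and neuron shares differed by 2.94 points (Fisher's exact p = 1). Against CpG-matched lists the neuronal genes still passed, with 33 marked and 23.3 expected (permutation adjusted p = 4.43e-05), whereas the progenitor genes, with 30.7 expected, did not (adjusted p = 0.0686). Genes of neurotransmitter and nucleus identity were marked in 18 of 24 cases (75%, Fisher's exact adjusted p = 0.318). Their highest values belonged to LIM homeobox genes, Lhx9 at 10.3 and Lhx5 at 9.84, and to Pou4f1 (9.43), a marker of the red nucleus and sensory neurons. Dbh, Fev and Phox2b, genes of noradrenergic, serotonergic and visceral motor neurons, were unmarked in the replicated list. Developmental signalling genes were marked in 47 of 49 cases (95.9%, Fisher's exact adjusted p = 7.04e-07), with the Wnt receptor gene Fzd3 (30.9), the Hedgehog pathway genes Smo (29.7) and Ptch1 (28.4) and the receptor gene Bmpr1a (28.2) highest. The retinoic acid enzymes Aldh1a2 and Cyp26a1 were its unmarked members.

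Markers of cell types that enter or surround the midbrain were marked unevenly. Blood vessel genes were marked in 12 of 20 cases (60.0%), the strongest being the glucose transporter gene Slc2a1 (14.0), while Kdr, the endothelial VEGF receptor, had 6.75 and Cdh5, Emcn and Pecam1 were unmarked. Erythroid genes were marked in 7 of 17 cases (41.2%), including the transferrin receptor gene Tfrc (15.6) and the erythroid factor Klf1 (8.10), and mesenchymal and neural crest genes in 19 of 27 (70.4%), with Prrx2 (8.48) and Twist1 (8.06) highest. Genes of later glia were marked in 9 of 20 cases (45.0%), led by the gliogenic factors Nfib (22.6) and Nfia (19.4), and those of surface epithelium in 8 of 16 (50%), led by Grhl2 (7.59). None of these 5 lists differed from other genes (Fisher's exact adjusted p from 0.108 to 0.816). In the most significant 50% of peaks the erythroid (23.5%), later glial (30%) and mesenchymal (37%) lists fell below other genes (Fisher's exact adjusted p = 0.00807, 0.018 and 0.041). The erythroid list also did so within 500 bp of a start and at annotated 5' ends, at 29.4% in each (Fisher's exact adjusted p = 0.00713 and 0.0178). Microglial genes were below other genes, at 3 of 20 (15%, Fisher's exact adjusted p = 1.52e-05, but permutation adjusted p = 0.142 against CpG-matched lists; 25% in replicate 1 alone and within 2500 bp, 10% in replicate 2 alone and in the most significant 50% of peaks, and 5% at annotated 5' ends), the marked ones being the macrophage factors Irf8 (6.56) and Runx1 (5.88) and Aif1 (2.93), which had no promoter peak in replicate 2. Liver, gut and pancreas genes were marked in 4 of 24 cases (16.7%, Fisher's exact adjusted p = 4.98e-06) and muscle genes in 5 of 22 (22.7%, Fisher's exact adjusted p = 0.000239), and in replicate 1 alone the muscle share was 45.5% (adjusted p = 0.0916). The highest value of each of these lists lay in a promoter peak shared with a neighbouring gene, that of Foxa3 (19.8) with Sympk and that of Mylpf (17.2) with Tbc1d10b. Prox1 (9.53) in the liver list and Myh7 (6.83) in the muscle list followed, in peaks of their own.

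Genes that every dividing cell uses were marked throughout. All 33 cell cycle genes, all 34 genes of histone acetylation and all 30 housekeeping genes carried a replicated promoter peak (Fisher's exact adjusted p = 1.26e-06, 1.26e-06 and 4.98e-06). The highest cell cycle values were at Cdk4 (32.8), which drives entry into S phase, at the ribonucleotide reductase gene Rrm2 (27.5) and at Mki67 (23.8). Among the writers, erasers and readers of acetylation, Brd2 reached 32.5 in a peak shared with H2-DMa, the acetyltransferase gene Ep300 32.1, and the deacetylase genes Hdac7 and Hdac2 28.6 and 28.4. Against CpG-matched lists the acetylation and housekeeping genes still passed (permutation adjusted p = 0.00179 and 0.0159), and the cell cycle genes did not (0.315). Ribosomal protein genes were marked in 79 of 82 cases, which did not pass against CpG-matched lists (75.1 expected, permutation adjusted p = 0.0882), and mitochondrial ribosomal protein genes in 78 of 78, although only 56.4% of the latter stayed marked, no longer past the threshold, when promoter peaks shared with a neighbouring gene were left out (Fisher's exact adjusted p = 0.404). Zfp zinc finger genes were marked in 337 of 394 cases (85.5%, Fisher's exact adjusted p = 1.35e-20). Receptor families of the nose were nearly blank: 1 of 1134 olfactory receptor genes and 1 of 328 vomeronasal receptor genes were marked. Keratins and their associated proteins were marked in 8 of 110 cases (Fisher's exact adjusted p = 3.32e-35), and beta-defensins and interleukin receptors in 19 of 83 (adjusted p = 1.02e-13). The clustered protocadherins, neuronal adhesion genes with alternative promoters, were marked in 8 of 54 cases (14.8%, Fisher's exact adjusted p = 3.93e-13), although their CpG content gave an expectation of 40.2 (permutation p = 1e-05, the smallest possible). The Sox, Fox and homeobox families had 15 of 19, 34 of 44 and 48 of 64 members marked and did not pass the threshold (Fisher's exact adjusted p from 0.117 to 0.268). Their CpG content gave higher expectations, 17.2, 37 and 51.9 marked members. Against CpG-matched lists none of them passed (permutation adjusted p = 0.0804, 0.216 and 0.208). In replicate 1 alone all of these families passed, at 94.7%, 84.1% and 79.7% (Fisher's exact adjusted p = 0.00914, 0.00974 and 0.0232). The homeobox family also passed in the pooled list (78.1%, Fisher's exact adjusted p = 0.0379). With shared promoter peaks left out, the Sox and homeobox shares were unchanged at 78.9% and 75%. They then stood above the lowered share of other genes (Fisher's exact adjusted p = 0.0264 and 0.000254).

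Midbrain and progenitor regulators had broader acetylation domains than random marked genes. Nearly all of their members were marked, so breadth and presence of the mark cannot be weighed against each other. Peaks were joined into domains when at most 1 kb apart, and the median marked gene had a domain of 1727.5 bp (interquartile range 1162 to 2427). The midbrain and isthmus list had a median of 7590 bp (interquartile range 3554 to 10799), compared with 1726 bp for random sets of marked genes (central 95%, 1385 to 2122). Neural progenitor genes had a median of 5696.5 bp, Sox family genes 5722 bp, floor plate and dopaminergic progenitor genes 4847 bp, signalling genes 3568 bp, neuronal genes 3316 bp and homeobox family genes 2822.5 bp. For each of these the permutation p was 1e-05, the smallest possible with 100000 resamples (adjusted p = 3.71e-05 over 26 lists). Cell cycle, acetylation, housekeeping, ribosomal protein, Fox and later glial genes were also broader than random sets, with medians of 2250 to 2793 bp (adjusted p up to 0.0221). Fox genes did not pass for single peaks (1492.5 bp, permutation adjusted p = 0.54), nor did acetylation genes at annotated 5' ends or in the most significant 50% of peaks (2030 bp in each, permutation adjusted p = 0.177 and 0.0594). Domains of dopaminergic neuron genes (1811 bp, permutation adjusted p = 0.772) and forebrain genes (1592 bp, adjusted p = 0.58) were within the random range. Domains were narrower for protocadherins (530.5 bp), surface epithelium (640.5 bp), keratins (506 bp), defensins and interleukin receptors (954 bp), vessel genes (1055.5 bp) and Zfp genes (1560 bp; permutation adjusted p from 0.0105 to 0.05). Against CpG-matched sets the vessel, Zfp and keratin lists no longer passed (permutation adjusted p = 0.179, 0.297 and 0.059). Vessel genes also lost the call in the pooled list, in the most significant 50% of peaks, within 2500 bp, with a gap of 3 kb and in bins of transcript start number (permutation adjusted p from 0.0683 to 0.15), and Zfp genes for single peaks and in the start bins (permutation adjusted p = 0.626 and 0.0672). Defensins and interleukin receptors lost it in the most significant 50% (permutation adjusted p = 0.0742), and surface epithelium with a gap of 3 kb (permutation adjusted p = 0.0559). Of the 10 protein-coding genes with the widest promoter domains, 4 were midbrain list members, Otx2, Pax3, Meis2 and Otx1. The widest spanned 35137 bp over Nr2f1, from position 78169912 to 78205048 of chromosome 13, and the related orphan nuclear receptor gene Nr2f2 had a domain of 29018 bp. The neural POU factor genes Pou3f3 and Pou3f2 had domains of 30632 and 22747 bp, Sox2 20843 bp and Otx2 20837 bp. In the most significant 50% of peaks the dopaminergic neuron and forebrain genes that stayed marked had median domains of 3300 and 3178 bp (permutation adjusted p = 0.00044 and 0.0008), whereas as single peaks forebrain domains were narrower than random sets (832 bp, permutation adjusted p = 0.0116). The later glial list did not pass the threshold in replicate 2 alone, in the most significant 50% of peaks or with a gap of 3 kb, though its medians stayed near the main value (2559, 2370 and 2871 bp, permutation adjusted p = 0.0771, 0.0903 and 0.0541). In replicate 1 alone and at annotated 5' ends its medians were 1279 and 1665 bp, below those of random sets but not past the threshold (permutation adjusted p = 0.328 and 0.894), and as single peaks it did not pass either (1665 bp, permutation adjusted p = 0.412). Homeobox family domains did not pass in replicate 1 alone (1781 bp, permutation adjusted p = 0.343).

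**Figure D3:**
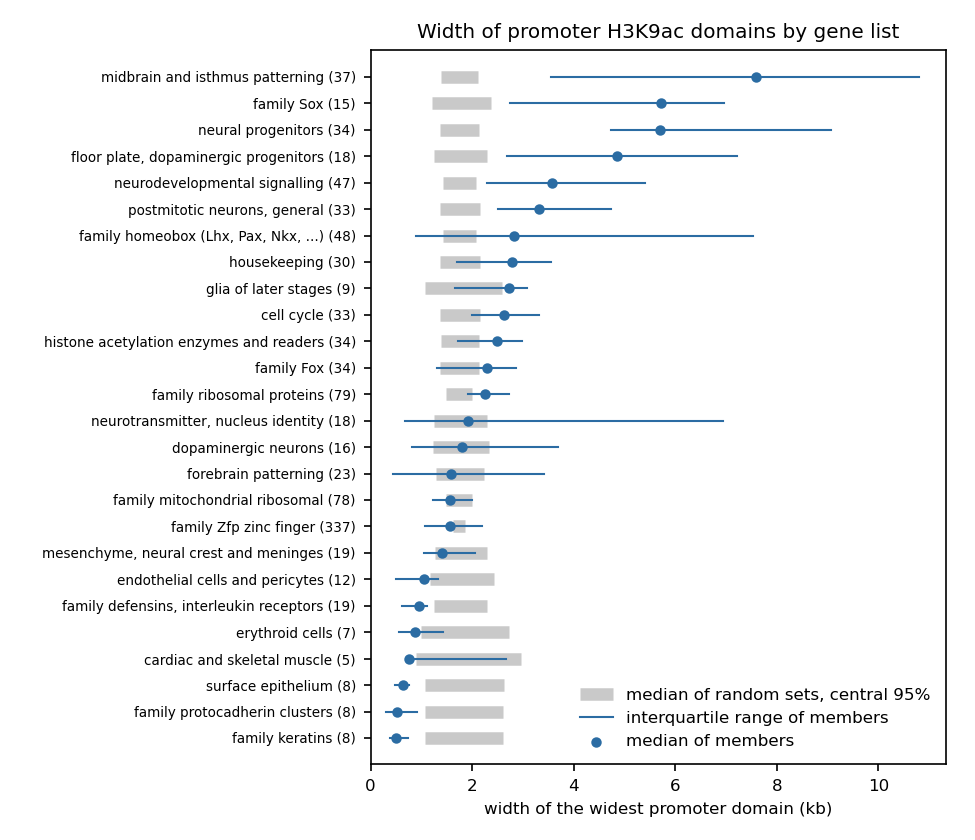
Width of the widest H3K9ac domain at each marked gene's promoters, in kb: median (points) and interquartile range (blue lines) of the members of each list, with the number of marked members in brackets, and the central 95% of medians of equally large random sets of marked genes (grey). The midbrain and isthmus list had the highest median, 7590 bp, against 1726 bp for random sets.

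Acetylation away from promoters was densest around midbrain, progenitor and Sox family genes, but was not confined to regulators. Of the replicated peaks on the assembled chromosomes, 16173 (45.9%) lay more than 1 kb from every protein-coding start, with a median width of 398 bp, a median enrichment of 3.54 and a median distance of 14.6 kb to the nearest start. Midbrain and isthmus genes were nearest to 303 of them, 7.97 per gene, compared with a median of 46 for random lists of genes with equally large surroundings (permutation p = 1e-05, the smallest possible, adjusted p = 7.75e-05). Neural progenitor genes were nearest to 250, compared with 38 (permutation adjusted p = 7.75e-05), Sox family genes to 166, compared with 21 (adjusted p = 0.000124), homeobox family genes to 241, compared with 71 (adjusted p = 0.00031), and signalling genes to 234, compared with 66 (adjusted p = 0.000443). Expected counts in this paragraph are medians of the random lists. Floor plate and dopaminergic progenitor genes (88 peaks, 27 expected), dopaminergic neuron genes (80, 24 expected) and general neuronal genes (119, 39 expected) also had more than random lists (permutation adjusted p = 0.0176 for each), as did forebrain genes (73, 29 expected, adjusted p = 0.0351). So did Fox genes (125, 41 expected, permutation adjusted p = 0.0149), Zfp genes (402, 1.57 times the median of random lists, permutation adjusted p = 0.00647), cell cycle genes (47, 15 expected) and ribosomal protein genes (84, 35 expected, permutation adjusted p = 0.0176 for both). The random lists were drawn from all protein-coding genes, marked or not. Part of an excess may therefore go with a list being marked at its promoters, which was not tested. Distal peaks were counted as single peaks, so the outer peaks of a broad promoter domain could be among them. Domain widths and distal counts are thus not separate results, and how many peaks enter both was not measured. Within the midbrain list Pax7 had 23 such peaks, Otx2 22, Lmx1b 18 and En1 16. Otx2 and En1 are also in the dopaminergic neuron list, where they had the highest counts and 9 of 19 members had any distal peak. Their peaks are thus part of the 80 counted for that list. The list was not tested without Otx2 and En1, so an excess is not shown for its other members. Hox genes were nearest to 4 distal peaks in all (9 expected, permutation adjusted p = 0.456). Olfactory receptor genes (25 peaks, 375 expected) and vomeronasal receptor genes (10, 217 expected) had fewer than random lists (permutation adjusted p = 7.75e-05 for both). The genes with most distal peaks were Gse1 (107), the zinc finger genes Zfp608 (45) and Zfp36l1 (41), the Rap exchange factor gene Rapgef5 (40) and Zfhx3 (40). By their symbols Zfp608 and Zfp36l1 belong to the Zfp family, in which 113 of 394 members had any distal peak. Their peaks are part of the 402 counted for that family. It was not tested without them, so an excess is not shown for its other members. The distal peak with the highest enrichment, 45.2, spanned positions 73556641 to 73558707 of chromosome 7, between genes and 15.8 kb from the nearest protein-coding start, that of the chromatin remodeller gene Chd2. The next ones were nearest to Mon2 (41.0), Setd1b (41.0), Mef2c (36.0) and Slc38a10 (35), and each of these 5 peaks lay within 1 kb of the start of an annotated gene that is not protein-coding. With distal peaks counted only beyond 5 kb, the floor plate and dopaminergic progenitor list (50 peaks, permutation adjusted p = 0.108) and the forebrain list (47 peaks, adjusted p = 0.133) no longer passed, nor did the cell cycle list (21 peaks, adjusted p = 0.151), and beyond 2500 bp the forebrain and cell cycle lists did not either (permutation adjusted p = 0.0816 and 0.0596). In replicate 1 alone the forebrain and Zfp lists did not (permutation adjusted p = 0.0961 and 0.145), and in the most significant 50% of peaks the forebrain, cell cycle and ribosomal protein lists did not (permutation adjusted p = 0.105, 0.0881 and 0.214).

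**Figure D4:**
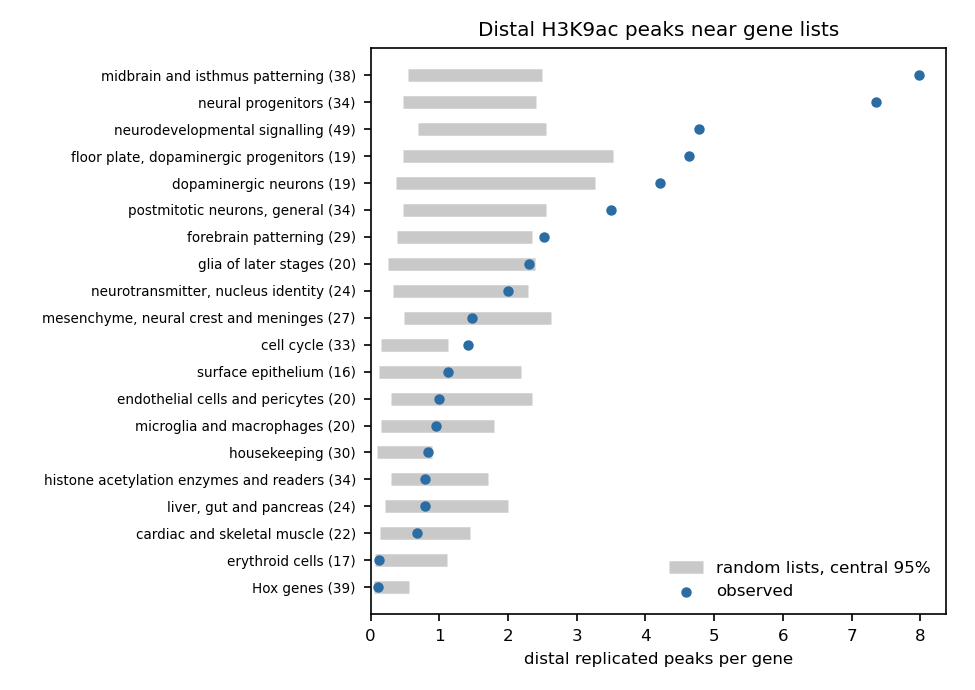
Distal replicated H3K9ac peaks per gene, by nearest protein-coding transcript start, for the members of each gene list (points, number of members in brackets) and the central 95% of random lists of genes, marked or not, matched on the size of the genes' surroundings (grey). Midbrain and isthmus genes had 7.97 peaks per gene and neural progenitor genes 7.35.

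Genes on the X chromosome were marked less often than autosomal genes in these pools of male and female embryos. Of 948 X-linked protein-coding genes 453 were marked (47.8%), compared with 13612 of 20807 autosomal genes (65.4%, Fisher's exact test, two-sided, p = 2.16e-27), a difference of -17.6 points. Marked X-linked genes had a median enrichment of 7.93. Among the X-linked list members Arx, a homeobox gene, had a weak promoter peak (3.29), and the erythroid genes Alas2 and Gata1 had none. These genes do not stand for all X-linked list members. The progenitor, housekeeping and acetylation lists, marked throughout, also hold X-linked genes. The X also carried more genes with a copied promoter, 187 genes (19.7%) against 893 autosomal genes (4.29%), and 3 of the 187 were marked. Without these the shares were 59.1% and 68.1%, a difference of -9 points (Fisher's exact p = 3.18e-07). With CpG-matched autosomal genes as the background as well, 450 of 761 were marked and 471 were expected (central 95%, 453 to 489, permutation p = 0.0228), so most of the difference went with these 2 properties. Both comparisons were added after the data were examined.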

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

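The tests in this part were chosen before their results were seen, apart from the random sets matched on transcript start number, which were added after the data were examined. The 2 samples form 1 group, so neither a single sample nor a group was tested against others.

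Signal in sequence outside the comparisons was found on scaffolds not placed in a chromosome, which held 5 replicated peaks on 2 scaffolds. This passed a fixed limit of 3 peaks used as a flag. The limit is not a background for these scaffolds, so the count does not show an unexpected signal. The list of replicate 1 held 5 such peaks and that of replicate 2 held 6, with 4 in each list on a scaffold assigned to the X chromosome. The highest enrichment in the replicated list was 16.7, and genes on these scaffolds were not in the gene set used here.

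Promoter domains of the midbrain and isthmus list had a median width of 7590 bp. The CpG ratio within 500 bp of the 5' end did not account for this. Random marked genes drawn within bins of it had a median of 1828 bp (central 95%, 1506 to 2206). CpG content beyond that window was not measured, so its part in the width stays open. The number of annotated transcript starts was no greater in the list (median 3, against 5 for all marked genes), and sets matched on it had a median of 1661 bp (1301 to 2062). Joining neighbouring peaks was part of the width but not all of it, as the median was 4001 bp for single peaks, with a permutation adjusted p of 0.00052. Cell type mixture and antibody efficiency at these genes stay open, and no biological explanation was tested because the design holds no second group.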

How the results depend on the processing

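The omission of shared promoter peaks, the bins of transcript start number and the X comparisons without receptors or copied promoters were chosen after the data were examined. Of 746 values of single lists under the alternatives, 676 kept their side of the threshold, 38 fell below it, 26 passed it and 6 reversed. Of 40 values of the 5 list pairs, 37 kept their side. The marked status of 178 named genes changed in 68 of 1424 cases, over 55 genes. Causes were not tested where none is given.

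Shared peaks of replicates 1 and 2 were 64.7% and 61.2% with any overlap of 1 bp, 38% and 43.9% with 50% of both peaks, 81.8% and 79.5% among the most significant 50%, and 87.6% and 75.3% with the same number of top peaks. Spearman's rho was 0.92 with 50% of both peaks. The promoter share of peaks was 42 to 42.1% with 1 replicate left out, 49% in the pooled list, 81% in the most significant 50%, 50.3% within 500 bp and 61.7% within 2500 bp. The CpG difference between marked and unmarked promoters was 0.534 to 0.535 with 1 replicate left out and 0.531 in the most significant 50%. Marked genes numbered 12726 to 14345 over the 7 alternatives in which all genes were counted, which did not include the omission of shared promoter peaks.

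Lists above the threshold in marking fell from 11 to 6 in CpG bins. Narrow lists fell from 6 to 2 in the most significant 50% and to 3 in CpG bins. In the most significant 50% only vessel genes and defensins and interleukin receptors lost the call in a test. The other lists missing from that count had fewer than 5 marked members and were not tested. The midbrain list exceeded the forebrain list by 57.9 points in the most significant 50% and by 26.7 points at 5' ends (adjusted p from 5.9e-06 to 0.125 over 8 alternatives), and dopaminergic progenitors exceeded dopaminergic neurons by 36.8 points in the most significant 50%. Forebrain and mesenchymal genes were marked in 31% and 37% of cases in the most significant 50%, below other genes, and forebrain domains were then wider, at 3178 bp, but narrower than random as single peaks, at 832 bp. Later glial domains were narrower than random, though not past the threshold, at 1279 bp without replicate 2 and 1665 bp at 5' ends, and were 2559 bp without replicate 1, no longer past it, and neurotransmitter domains were narrow as single peaks (877.5 bp) but broad in the most significant 50% (3736 bp) and within 500 bp (2428 bp). The X difference was -22.1 to -9 points in 9 alternatives, but with CpG matching and copied promoters left out together 450 genes were marked and 471 expected. Widths of the midbrain list stayed past the threshold in all 11 alternatives (4001 to 10292 bp), and its distal peaks in all 6 (68 to 446). What depth limits was not tested, as read totals are unknown.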

Other observations

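The genes below were named after their values were seen, and the tests of regulator families at CpG-rich promoters, with and without Hox genes, and of both X chromosome corrections together were chosen only after the result was seen.

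Promoters of genes that are not protein-coding accounted for part of the strongest distal acetylation. Of the 100 distal peaks with the highest enrichment, 65 lay within 1 kb of a noncoding start and 52 within 1 kb of that of a long noncoding RNA, compared with 10.3% and 7.41% of all 16173 distal peaks. The peak near Mon2 lay at the start of D630033A02Rik and of the let-7 microRNA gene Mirlet7i, that near Mef2c at C130071C03Rik, a long noncoding RNA gene, and that near Chd2 at 1810026B05Rik.

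CpG-rich promoters without a replicated peak were few. In the upper 2 CpG bins 210 of 8775 genes (2.39%) were unmarked, of which 45 had a promoter peak in 1 replicate's list and 5 in both. Single genes among them, picked by eye and not tested as groups, were the germline genes Ddx4, Dmrt1, Sycp1 and Mael and the regulators Cdx1, Hand2, Wt1 and Ptf1a. Within the protocadherin clusters the strongest marked members were Pcdhgc3 (9.92) and Pcdhgc4 (5.67), of the gamma cluster's C type.

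Regulators of other tissues were examined as a hypothesis for these promoters, which the values do not decide. The Hox, homeobox, Fox and Sox families made up 14.3% of unmarked and 0.759% of marked genes, but 20 of their 30 unmarked genes were Hox genes, already seen to lack peaks, so this share restates that result. With Hox genes left out they made up 5.26% (10 genes, Fisher's exact p = 4.46e-06), whereas the planned CpG-matched tests of the Sox, Fox and homeobox families did not pass (permutation adjusted p = 0.0804, 0.216 and 0.208). Genes with a copied promoter made up 18.1% of unmarked and 0.374% of marked genes, so they were overrepresented but did not account for most of the 210. Neither property applied to 142 genes, and their lack of a peak stays open.

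Fewer marked genes on the X chromosome were weighed against composition. Promoter CpG content alone left a gap, since CpG-matched autosomal genes gave 531 marked genes (central 95%, 510 to 552) and the X had 453. Copied promoters alone also left it, with 59.1% of the remaining X genes marked against 68.1% of autosomal genes (Fisher's exact p = 3.18e-07). Both together took most of it away: 471 were expected (453 to 489) and 450 were marked, just below that range (permutation p = 0.0228). A candidate explanation for the rest is that each cell has a single active X chromosome, and marked X promoters did have a lower median enrichment, 7.93 against 11.7 for CpG-matched autosomal ones (central 95%, 10.9 to 12.4), which remains a hypothesis because the sexes were pooled and copy number was not separated from activity.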
